A study of Mus musculus with 12 samples.

How the data were processed

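MeRIP-seq of polyA RNA from E14TG2a mouse embryonic stem cells was analysed for 3 genotypes, WT, Alkbh5 KO and Alkbh5 del-cIDR, with 2 input and 2 IP samples each. Per the labels' protocols, cells grew with LIF and inhibitors of MEK and GSK3, RNA was fragmented, and libraries were made with a stranded total RNA kit. The submitters' processing notes name fastp, HISAT2, SAMtools, Picard, MACS2, featureCounts and bedtools, without roles or versions, and the genome build GRCm39. The 2 deposited tables hold values for the whole series, and every per-sample column was matched to a sample by its label.

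The deposited m6A values are a ratio, IP over input per peak, multiplied by 1 constant per library. This was read from the values, not from a label: between 98.6% and 99.6% of a library's values equalled its constant times a ratio of whole numbers (relative tolerance 1e-10, denominators up to 3000), where 0.20% to 0.37% would by chance. The table has 1 common set of 12923 peaks, and a control named as m6A, covering positions 1 to 603, has the value 4.10 in every library, so the libraries are scaled to it. The file is named as CPM. The values are ratios and not CPM themselves, but a ratio of IP CPM to input CPM, times 1 constant per library, would have the same form. In lowest terms the median peak rested on 63 to 121 input reads and 195 to 277 IP reads, which are lower bounds. Peak positions are given in GRCm39, counted from 1.

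The deposited mRNA values are a signal: reads per gene times 1 factor per input library, from 2.98 to 1. In KO replicate 2 the factor is 1, so its deposited values are counts. All values (100%, tolerance 0.001 reads) came out as whole reads after division by the factor. Each factor equals 1273 divided by a whole number, which is 427 and 602 in WT, 1031 and 1273 in KO, and 459 and 547 in del-cIDR. The same numbers appear as input reads of the m6A control in the other table, whose IP reads were 3327, 4277, 5138, 5524, 3211 and 4562 in the same order. The mRNA values are therefore reads relative to those of the control RNA. Counting error of that control alone is 2.8% to 4.8% per library, and it does not include how evenly the control was added. How the control was added is not given in the sources used here.

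The design fixed before the data were examined assumed normalized values per feature. limma 3.58.1 (R 4.3.3) was fitted to log2(value + 1) for features with a mean of at least 1, with all 3 genotypes in 1 fit, an eBayes variance trend, and Benjamini-Hochberg adjustment at 0.05. A fold change on this scale understates the change of low features. This left 9451 peaks and 29059 genes. A ratio and control-scaled reads are both tested on the log scale, so the planned test was kept. The overall shift is the median over features of the difference between genotype means. Because the deposited scaling moved the median of all genes by up to 0.87, calls after centring each library on its median stand beside the deposited scale throughout. edgeR 4.0.16 (quasi-likelihood, TMM) and DESeq2 1.42.0 were run on the recovered reads, and edgeR also with the deposited factors. edgeR's biological coefficient of variation was 5.7%.

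Named features were fixed by rule: past the threshold, with no overlap between replicates, at or above the median level, the largest changes in each direction, and where none passed, the 3 smallest p in each direction. The symbol clause of that rule could not be applied. The reference table given, of 49997 genes, matched 0 of the gene identifiers to a symbol and is of an earlier build, so peak annotation, the 31 gene lists fixed by symbol, values under the name Alkbh5, and the relation of m6A to mRNA per gene were not analysed here. Comparisons that share WT libraries were set against simulations of unchanged groups with the replicate spread, and against the product of list lengths over the genes tested. Replicates of a genotype were not copies: their reads differed by 3.02 to 6.50 times the sampling variance.

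The fits were tested on simulated data for KO against WT, with 100 features changed at each size. Changed genes were drawn only from those above a minimum of mean reads, and every gene got the same coefficient of variation. The rates for genes therefore do not describe genes with few reads. With exact scaling, 80% of genes changed 2-fold and 97% of those changed 4-fold were recovered in a fit of 29059 genes. With the replicate spread of the deposited factors, 0% and 74% were recovered, after centring 89% and 100%, and with edgeR 93% and 100%. For 9451 peaks, 18% and 74% were recovered. Alternatives covered pseudocounts, filters, centring, quantile normalization, the variance trend, pairs of genotypes, a replicate block, other tools, and leaving out each library, where a lone library was assumed to vary like the other groups. Intervals and counting errors cover counting only, since the labels name no molecular identifiers. Tables and plots were made with Python 3.11.15, pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1 and Matplotlib 3.10.9.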

Results

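Methylation of adenosine at the N6 position (m6A) was profiled in mRNA of E14TG2a cells, a mouse embryonic stem cell line, by MeRIP-seq, in which fragmented polyA RNA is immunoprecipitated (IP) for m6A and sequenced beside the RNA before precipitation (input). The cells were wild type (WT), lacked Alkbh5 (KO), or carried an Alkbh5 without its C-terminal intrinsically disordered region (del-cIDR). Alkbh5 is an enzyme that removes m6A from RNA. Each of the 3 genotypes had 2 input and 2 IP samples, 12 samples in 6 groups, and the comparisons ask how m6A and mRNA differ when the enzyme or its disordered region is missing. m6A was measured as an IP over input ratio at 12923 peaks with a median width of 455 bases, and mRNA as scaled reads of 56941 genes. The input libraries held 25105719 and 34035774 reads in genes for WT, 36678609 and 33014087 for KO, and 30978068 and 19918177 for del-cIDR. The labels do not say whether replicates came from separate cultures, so the spread between these samples, on which the p-values rest, may be technical. The fit took that spread partly or wholly from other peaks or genes of like level. The genes are listed by identifier without symbols, so no value is given here under the name Alkbh5.

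In KO cells most m6A ratios, scaled to the m6A control, lay above those of WT cells. Of the 9451 peaks tested, 78.7% had a higher mean in KO, with a median difference of 0.13 on the log2(ratio + 1) scale. The median over these peaks was 1.72 ± 0.09 in KO and 1.58 ± 0.08 in WT on that scale (SD, n = 2 each). The KO libraries, at 1.66 and 1.79, lay above the WT libraries, at 1.64 and 1.52, but the lower KO library and the higher WT library were closer to each other than either was to its replicate. With 2 libraries against 2, an exact two-sided permutation test cannot give a p below 0.333. Without KO replicate 2 the median difference was 0.07, and without WT replicate 2 it was 0.08. It was 0.20 without KO replicate 1 and 0.20 without WT replicate 1. Before the control's constant was applied, the direction was the reverse. The median ratio over all peaks was then 1.98 and 1.97 in KO, 3.04 and 2.43 in WT, and 2.53 and 3.02 in del-cIDR. Of the tested peaks, 5.26% were then higher in KO than in WT. Such unscaled ratios also move with the depth of the IP libraries, which was not analysed here. They therefore cannot show whether the direction rests on the control or on depth. The scaled difference was not limited to low or high peaks. It was 0.13 in the fifth of peaks with the lowest ratios (0.93 to 1.34) and 0.12 in the fifth with the highest (3.55 to 34.8). The added 1 shrinks changes of low ratios more, so these near-equal values do not show equal changes, and low peaks may have changed more.

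No single peak passed the test in KO against WT (limma, smallest adjusted p = 0.3299), although 1051 peaks had an unadjusted p under 0.05, of which 951 were higher in KO, where chance alone gives about 473. That count was 540 without KO replicate 2, 641 without WT replicate 2 and 1262 without KO replicate 1. After centring on library medians, 758 peaks had an unadjusted p under 0.05 and none passed (smallest adjusted p = 0.508). The 6 peaks with the smallest p in either direction are therefore given as values. On chromosome 2 (26909910 to 26910135, GRCm39) the ratio was 1.49 ± 0.11 in KO and 0.485 ± 0.036 in WT (SD, n = 2 each). On chromosome 3 it was 1.97 ± 0.46 against 0.617 ± 0.057 at 122522602 to 122523013, and 1.80 ± 0.29 against 0.639 ± 0.094 at 30752463 to 30752702. The peaks with lower values in KO were on chromosome 12 (84281977 to 84282327), with 2.00 ± 0.28 in KO and 6.38 ± 2.28 in WT, on chromosome 3 (133015558 to 133015881), with 1.40 ± 0.28 against 3.49 ± 0.70, and on chromosome 17 (37253580 to 37254273), with 1.31 ± 0.53 against 3.12 ± 0.09. Gene annotation of these positions was not used here. With a replicate block, which the labels do not call for, 59 peaks passed, 55 higher and 4 lower in KO. With only KO and WT in the fit, 9 peaks passed, 8 of them higher in KO. Without del-cIDR replicate 1 or 2, 9 or 10 passed.

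**Figure D1:**
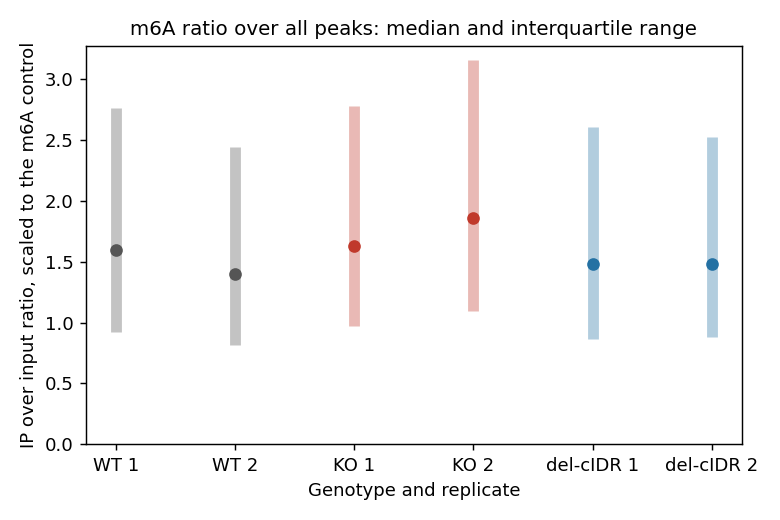
Median (points) and interquartile range (bars) of the scaled IP over input ratio over all 12923 peaks in each library, by genotype and replicate. The KO medians are 1.63 and 1.86, the WT medians 1.60 and 1.40, and the del-cIDR medians 1.48 and 1.49.

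In del-cIDR cells the median m6A ratio lay within the range of the WT libraries. The median difference from WT was -0.02 on the log2(ratio + 1) scale (0.05 without WT replicate 1, -0.07 without WT replicate 2), and 45.9% of the peaks had a higher mean in del-cIDR. Both del-cIDR libraries, with medians of 1.58 and 1.57, lay between the WT libraries. No peak passed the test (limma, smallest adjusted p = 0.579), and 543 had an unadjusted p under 0.05, where chance gives about 473. After centring there were 682 such peaks, and none passed (smallest adjusted p = 0.494). Among the peaks with the smallest p, the ratio on chromosome 5 (127436856 to 127437441) was 16.8 ± 4.23 in del-cIDR, 10.1 ± 1.98 in KO and 5.44 ± 0.79 in WT (SD, n = 2 each). The other peaks with higher values in del-cIDR than in WT were on chromosome 7 (125442144 to 125442456), with 1.66 ± 0.43 against 0.597 ± 0.171, and on chromosome 5 (48142347 to 48142553), with 1.28 ± 0.41 against 0.446 ± 0.060. Lower values were found on chromosome 2 (126517429 to 126517994), with 0.694 ± 0.072 in del-cIDR and 1.88 ± 0.06 in WT, on chromosome X (12522828 to 12523075), with 1.07 ± 0.47 against 2.90 ± 0.02, and on chromosome 15 (93398071 to 93398607), with 1.59 ± 0.06 against 3.67 ± 0.56. Without del-cIDR replicate 1 or 2, 3 peaks or 1 peak passed. Among peaks with a mean ratio of at least 10, 1 peak passed. With a replicate block 13 passed, 7 higher and 6 lower in del-cIDR.

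Set directly against KO, the del-cIDR cells had lower ratios at most peaks: 19.7% of peaks had a higher mean in del-cIDR, and the median difference was -0.15, or -0.08 without KO replicate 2. Before the control's constant was applied, 94.8% of the peaks were higher in del-cIDR than in KO. Those unscaled ratios also move with library depth, so they cannot show whether the direction rests on the control. Both del-cIDR library medians lay below both KO medians. No peak passed (limma, smallest adjusted p = 0.160), and 1112 had an unadjusted p under 0.05, of which 986 were lower in del-cIDR. Without KO replicate 2 the count was 594. After centring there were 811 such peaks, and none passed (smallest adjusted p = 0.441). The lowest p belonged to a peak on chromosome 1 (182871040 to 182871304), at 0.542 ± 0.187 in del-cIDR, 1.82 ± 0.06 in KO and 1.01 ± 0.06 in WT (SD, n = 2 each). A peak on chromosome 7 (4946539 to 4947261) had 1.13 ± 0.06 in del-cIDR and 3.35 ± 0.38 in KO, and a peak on chromosome 12 (9019607 to 9020597) had 1.04 ± 0.07 and 4.01 ± 1.38. Higher values in del-cIDR than in KO were found on chromosome 9 (123247459 to 123247707), with 1.52 ± 0.28 against 0.697 ± 0.095, on chromosome 14 (76723005 to 76723488), with 3.34 ± 0.50 against 1.68 ± 0.10, and on chromosome 5 (122377999 to 122378201), with 1.68 ± 0.78 against 0.507 ± 0.009. With a mean ratio of at least 10, 1 peak passed, and with a replicate block 109 passed, 11 higher and 98 lower in del-cIDR. On data simulated at this spread for KO against WT, the fit without a block recovered 18% of peaks changed 2-fold and 74% changed 4-fold. Most 2-fold changes of a single peak would therefore be missed.

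The deposited mRNA values of KO cells were lower than those of WT cells for most genes. The median difference over 29059 tested genes was -0.87 on the log2(value + 1) scale, and 512 genes fell while 7 rose (limma, adjusted p under 0.05). The deposited values summed to 45287943 and 33014087 in the KO libraries and to 74846792 and 71972658 in the WT libraries, although KO had on average more reads. The scaling followed the input reads of a control RNA, of which there were 1031 and 1273 in KO, 427 and 602 in WT, and 459 and 547 in del-cIDR. Every library was then centred on its own median, so that a gene was compared with the other genes of its library. After this, 1960 genes rose and 1867 fell. Centring takes the same amount from every gene of a library, although low genes had moved less on the deposited scale. The median deposited difference was -0.36 in the 7265 genes with the lowest means and -0.92 in the 7265 with the highest. Centring thus lifts low genes in KO: 55 of the lowest rose and 0 fell, against 984 and 999 of the highest. Of the 519 genes called on the deposited scale, 465 were also called after centring, all 465 in the same direction.

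**Figure D2:**
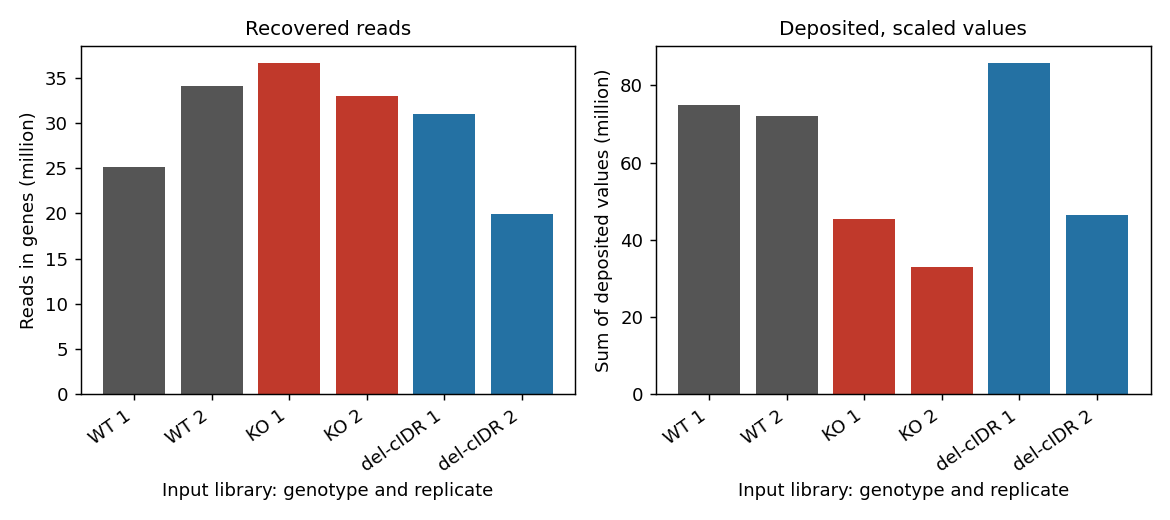
Reads in genes (left) and the sum of the deposited scaled values (right) for each input library. The KO libraries hold 36678609 and 33014087 reads and sum to 45287943 and 33014087 after scaling, while the WT libraries sum to 74846792 and 71972658.

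The files do not pair gene identifiers with symbols, so no more than 2 genes that rose and 2 that fell are given per comparison. ENSMUSG00000035910 fell from 295 ± 16.8 scaled reads in WT to 8.79 ± 6.78 in KO (SD, n = 2 each), a log2 change of -5.12 (SE 0.61, limma adjusted p = 4.83e-13). ENSMUSG00000022054 fell from 2098 ± 344 to 92.5 ± 33.3, by -4.53 (SE 0.51, adjusted p = 1.66e-14). ENSMUSG00000046879 rose from 22.9 ± 15.5 to 179 ± 33.6, by 3.07 (SE 0.73, adjusted p = 0.00602). ENSMUSG00000028023 rose from 122 ± 50.4 to 497 ± 94.1, by 2.06 (SE 0.57, adjusted p = 0.0285). All 4 passed after centring too, in the same direction. For the genes named on the deposited scale, the unadjusted p equals that of a normal distribution for the change over its SE. The SE thus came from genes of like level and not from the gene's own replicates, and the very small p-values rest on that.

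After centring, the genes that rose in KO had a median log2 change of 0.52, and those that fell a median of -0.50. Among them 454 rose and 348 fell at least 2-fold on that scale. The 198 genes that rose at least 4-fold had a median of 16.3 reads per library in KO and 2 in WT, and 140 of them passed with edgeR as well. The 83 genes that fell at least 4-fold had a median of 7 reads in KO and 34 in WT, and 82 of them passed with edgeR. The 519 calls on the deposited scale ended when any 1 library was left out, when only KO and WT were fitted, or when the variance trend was not modelled (0 genes each, with 1005 to 13860 genes at an unadjusted p under 0.05), and with no filter on low values their balance turned, to 170 that rose and 114 that fell. The centred calls held in number with edgeR on the recovered reads (2637 higher, 2509 lower), but without KO replicate 1 or 2 they were 2066 or 1960, and without the variance trend 0. Their balance moved with the WT library, to 1497 higher and 1952 lower without WT replicate 1 and 2338 and 1439 without WT replicate 2.

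In del-cIDR cells 6 genes fell against WT and none rose on the deposited scale (limma). edgeR with the deposited factors gave 0 calls. An unadjusted limma p under 0.05 was found for 1378 genes, fewer than chance alone gives over 29059 genes. ENSMUSG00000042650 fell from 10374 ± 723 scaled reads in WT to 2128 ± 594 in del-cIDR (SD, n = 2 each), a log2 change of -2.31 (SE 0.49, limma adjusted p = 0.0215). It stood at 2210 ± 429 in KO, a log2 change of -2.24 (adjusted p = 0.00212), and was the 1 gene called in both KO and del-cIDR on this scale. ENSMUSG00000005892 fell from 1772 ± 18.2 in WT to 318 ± 163 in del-cIDR, by -2.58 (SE 0.50, adjusted p = 0.00633), and had 2393 ± 555 in KO. The median difference over all genes was -0.23, but the del-cIDR libraries differed from each other by 0.87, and without replicate 2 the median difference was 0.23, on the other side of 0, and without replicate 1 it was -0.70.

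After centring, 729 genes rose and 672 fell in del-cIDR against WT, and all 6 genes called before were among them. Their median log2 changes were 0.43 and -0.52. edgeR on the recovered reads called 1067 higher and 1190 lower. The centred calls were 290 higher and 631 lower without del-cIDR replicate 1, 256 and 265 without del-cIDR replicate 2, 548 and 830 without WT replicate 1, and 1036 and 442 without WT replicate 2. They numbered 569 with a pseudocount of 0.1 and 0 without the variance trend. The 6 calls on the deposited scale were 0 when any 1 library was left out, and with no filter 49 genes rose and 3 fell.

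Between the altered genotypes, 441 genes were higher and 29 lower in del-cIDR than in KO on the deposited scale (limma). ENSMUSG00000068457 had 1035 ± 427 scaled reads in del-cIDR, 18.9 ± 1.24 in KO and 442 ± 86.0 in WT (SD, n = 2 each), with a log2 change of 5.64 between del-cIDR and KO (SE 0.56, limma adjusted p = 1.02e-19). ENSMUSG00000035910, which fell in KO, had 451 ± 276 in del-cIDR, a log2 change of 5.58 from KO (SE 0.61, adjusted p = 3.57e-16). ENSMUSG00000046879 and ENSMUSG00000005892 were lower in del-cIDR than in KO, by -4.29 (SE 0.73, adjusted p = 5.03e-06) and by -2.99 (SE 0.50, adjusted p = 2.27e-06).

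After centring, 3199 genes were higher and 2751 lower in del-cIDR than in KO, more than in either comparison with WT. Among the 7265 genes with the lowest means, where centring lifts KO, 1 was higher and 60 were lower in del-cIDR. On the first principal component of the centred values, which held 26.1% of the variance, the KO libraries lay at 0.50 and 0.49, the WT libraries at -0.01 and -0.02, and the del-cIDR libraries at -0.63 and -0.33. On the second, with 24.4% of the variance, WT replicate 1 stood apart at 0.89, WT replicate 2 lay at 0.01, and the other libraries between -0.30 and -0.14. The 470 calls on the deposited scale were 6929 without del-cIDR replicate 2 and 0 without any other library, and with no filter 55 genes were higher and 169 lower. The centred calls were 3683 without KO replicate 1, 3734 without KO replicate 2 and 0 without the variance trend, and without del-cIDR replicate 1 they were 2316 higher and 2684 lower.

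After centring, genes called in both altered genotypes moved in opposite directions more often than in the same direction, while on the deposited scale 1 gene was called in both. Of the centred calls, 186 genes rose in KO and fell in del-cIDR, 177 fell in KO and rose in del-cIDR, 127 rose in both and 73 fell in both. Independent lists of these lengths would share 92.2 genes in opposite directions and 92.3 in the same direction. This takes every tested gene as equally likely to be called, but calls lay mostly in genes with high means. Among the 7265 genes with the highest means, 984 rose and 999 fell in KO, and 407 rose and 325 fell in del-cIDR. Among the 7265 with the lowest, these were 55, 0, 10 and 1. Chance overlap is therefore larger than the values for independent lists, in both directions. In 20 simulations of unchanged groups against the same WT libraries no gene was called in either comparison, so they give no overlap to compare with. edgeR gave 679 genes in opposite and 386 in the same direction. With a separate WT library for each comparison, 434 genes were opposite and 154 the same when KO was set against WT replicate 1 and del-cIDR against WT replicate 2, and 360 and 127 with these exchanged. With a single WT library for both, whose chance values then enter both comparisons in full, there were 268 opposite and 273 the same without WT replicate 1, and 274 and 341 without WT replicate 2. A group of 14 genes with log2 changes of at least 2.5 in both genotypes had at most 8 reads in a WT library and 2 to 30 in the others, and edgeR called 1 of them in both comparisons.

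**Figure D3:**
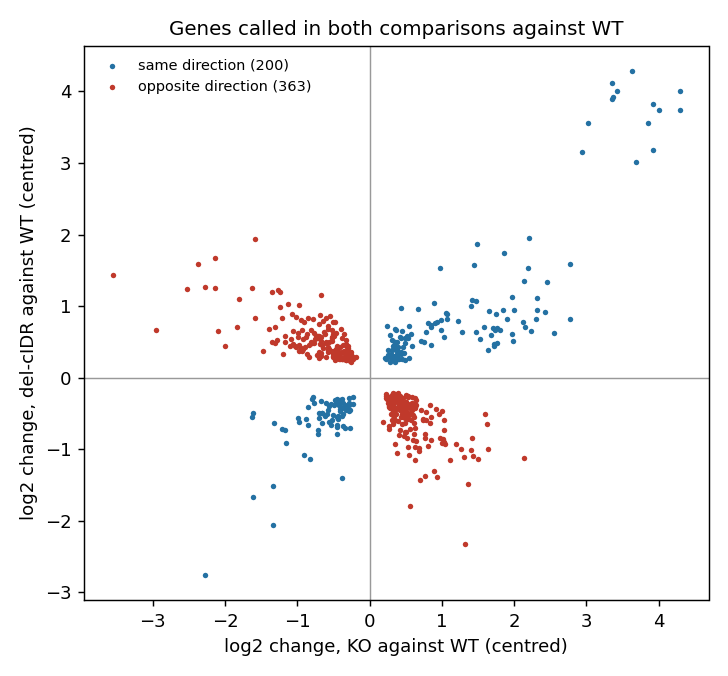
Centred log2 change of mRNA in KO against WT (horizontal) and del-cIDR against WT (vertical) for the 563 genes called in both comparisons, each point a gene. The 363 genes in red changed in opposite directions and the 200 in blue in the same direction, and the 14 genes at the upper right had few reads.

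Across all tested genes the centred changes of KO and del-cIDR correlated with r = 0.45 (Spearman 0.28), where unchanged groups sharing the WT libraries gave 0.50 in 50 simulations. Genes are not independent replicates, so no p is given. The simulated r of 0.50 is set by the shared WT libraries and equal group sizes, whatever the data. Real changes in either genotype alone also move r away from it, so an r below 0.50 does not by itself show opposite changes. The covariance was 0.372 against 0.318 simulated, but the difference between the WT replicates alone gives 0.379, and with separate WT libraries it was -0.0007 or -0.0140. Among the 13529 genes with a mean of at least 100, a limit chosen after the data were seen, r was -0.06 against 0.50 simulated, and the covariance was -0.0065 against 0.0104. With a separate WT library for each comparison, r in these genes was -0.15 or -0.13. With a single WT library for both, the sign turned: r was 0.0365 without WT replicate 1 and 0.0338 without WT replicate 2. The m6A changes correlated with r = 0.46 (Spearman 0.44) against 0.50 in 100 simulations, with a covariance of 0.0194 against 0.0173, and with separate WT libraries r was 0.04 or 0.07 and the covariance 0.0026 or 0.0041. These splits rest on 1 WT library on each side.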

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

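The m6A table also holds an unmodified control, which no comparison uses. Its IP over input ratio was above 0 in every library. As a percent of the m6A control's ratio it was 1.29 in WT replicate 1, 0.488 in WT replicate 2, 0.245 in KO replicate 1, 0.475 in KO replicate 2, 0.532 in del-cIDR replicate 1 and 0.493 in del-cIDR replicate 2. This is signal outside the main measurement, above 0 where no m6A is expected from the control's name. WT replicate 1 had the highest value and KO replicate 1 the lowest. No explanation of these values was tested.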

How the results depend on the processing

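Added after the data were seen were edgeR with the deposited factors, the overall mRNA shift, the calls after median centring with their own alternatives, the correlation over genes with a mean of at least 100, the shared calls with 1 library left out or separate WT libraries, and the m6A ratios before the control constant. All other alternatives were planned. Unless stated, the cause of a change was not tested. Not run, because identifiers were not paired with symbols, were the m6A change minus the gene's mRNA change, 1 peak per gene, the gene lists fixed by symbol, m6A against mRNA change, and the level under the name Alkbh5. The ratio of IP to input per replicate is what the deposited values already hold, and count tools were not run on these ratios. With 1 library left out, the lone library of its group is assumed to vary like the other groups.

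For m6A the count of peaks was 0 in all 3 comparisons and stayed 0 under pseudocounts 0.1 and 5, no filter, centring, quantile normalization and no variance trend. It was 9 for KO against WT with only the 2 genotypes fitted, and 1 for del-cIDR against WT and 1 for del-cIDR against KO among peaks with a mean of at least 10. With 1 library left out it ranged from 0 to 10 for KO against WT, 0 to 3 for del-cIDR against WT and 0 to 5 for del-cIDR against KO. Peaks with an unadjusted p under 0.05 then ranged from 540 to 1262, from 445 to 738 and from 594 to 1364. The overall m6A shift of KO against WT moved to 0.0582 with pseudocount 5, and of del-cIDR against KO to -0.0635, since a larger pseudocount shrinks log changes. The other filters, pseudocount 0.1 and the mean over peaks kept the sign of both, while centring on library medians takes the shift out (-0.0036 and 0.0015). With 1 library left out they ranged from 0.0669 to 0.1987 and from -0.2099 to -0.0789. Before the control constant the median log2 change, without a pseudocount, was -0.48 for KO against WT, 0.01 for del-cIDR against WT and 0.50 for del-cIDR against KO. The shift of del-cIDR against WT ranged from -0.0689 to 0.0474 with 1 library left out.

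Libraries of the same replicate number did not deviate together peak by peak or gene by gene. The correlation r was between -0.03 and 0.02 over the 3 pairs of genotypes in both measures. Such a correlation cannot see a shift of a whole library. On the deposited mRNA scale, replicate 1 had the higher median in every genotype. The medians were 6.45 and 6.35 in WT, 5.72 and 5.25 in KO, and 6.57 and 5.71 in del-cIDR. For m6A the order was reversed in KO (1.66 and 1.79). With the replicate block, m6A calls were 59 (55 higher, 4 lower) for KO against WT, 13 (7, 6) for del-cIDR against WT and 109 (11, 98) for del-cIDR against KO. mRNA calls on the deposited scale were 3517 (56, 3461), 27 (1, 26) and 1364 (1284, 80). After centring, the block left the counts within 1.5 times.

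mRNA calls on the deposited scale, 519, 6 and 470 for KO against WT, del-cIDR against WT and del-cIDR against KO, changed as follows, in this order. They were 69, 0 and 135 with pseudocount 0.1. They were 284 (170 higher, 114 lower), 52 (49, 3) and 224 (55, 169) with no filter, against 7 and 512, 0 and 6, and 441 and 29 with it. They were 865 and 1 for the first 2 comparisons with a mean of at least 10. With pseudocount 5, del-cIDR against WT had 3. Without the variance trend all 3 were 0, and with only 2 genotypes fitted all 3 were 0. Centring gave 3827, 1401 and 5950 (1960, 729 and 3199 higher), quantile normalization 3582, 968 and 5614 (1790, 397 and 2875 higher), edgeR with TMM 5146, 2257 and 6931 (2637, 1067 and 3489 higher), and DESeq2 3520, 1358 and 5152 (1792, 602 and 2597 higher). edgeR with the deposited factors gave 614, 0 and 628. With 1 library left out, the counts ranged from 0 to 0, 0 to 0 and 0 to 6929. A limit of log2 change of at least 1 removed no call.

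The centred mRNA calls were 802, 212 and 1422 with a log2 change of at least 1 as well, and 0, 0 and 0 without the variance trend. Pseudocount 0.1 left 569 for del-cIDR against WT, and edgeR called 2257 there. With 1 library left out they ranged from 1960 to 4027, from 521 to 1478 and from 3683 to 6836. The overall mRNA shift, -0.87 for KO against WT and 0.62 for del-cIDR against KO, was 0 for both with no filter, where 24645 to 27463 of the 56941 genes had any read in a library. With 1 library left out it ranged from -1.106 to -0.659 for KO against WT, from -0.698 to 0.227 for del-cIDR against WT and from 0.165 to 1.104 for del-cIDR against KO.

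The correlation of KO and del-cIDR changes ranged from 0.346 to 0.636 for m6A and from 0.354 to 0.653 for mRNA with 1 library left out. With WT replicate 1 for KO and WT replicate 2 for del-cIDR it was 0.0437 for m6A and -0.0006 for mRNA, and with these exchanged 0.0715 and -0.0115, since separate WT libraries remove the shared values. Over genes with a mean of at least 100 it was -0.1544 and -0.1325 with separate WT libraries, and with 1 library left out it ranged from -0.0705 to 0.0365, above 0 without WT replicate 1 (0.0365) and without WT replicate 2 (0.0338).

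Over the named peaks and genes, no alternative turned a direction. Their side of the threshold stayed the same in 222 of the peak values, and 31 of them passed under an alternative. For genes it stayed the same in 88 and was lost in 92.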

Other observations

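The tests in this part were all chosen after the data were seen. Lists of 100 genes for each cell-cycle phase, taken by identifier from a published set of mouse phase markers, were set against the centred mRNA values, with 6 genes in more than 1 list. In del-cIDR against WT, 16 of the G2/M genes rose and 3 fell (limma, adjusted over all genes), with a mean log2 change of 0.07. The list was called by camera with a preset correlation of 0.01 (adjusted p = 0.00344 over 9 tests), and was not called with an estimated correlation (adjusted p = 0.980). In KO against WT, 14 G2/M genes rose and 8 fell (adjusted p = 0.904). For del-cIDR against KO, 32 rose and 16 fell (adjusted p = 0.134). The S list had 15 higher and 8 lower in KO, and 6 higher and 7 lower in del-cIDR, and the G1 list 11 and 11, and 8 and 3. For del-cIDR against KO, 15 S genes rose and 17 fell, and 23 G1 genes rose and 11 fell. None of these other lists was called.

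Counting genes that differed from both other genotypes after centring, KO stood above both for 1438 genes and below both for 1534. del-cIDR stood above both for 500 genes and below both for 525, and WT above both for 73 and below both for 127. With edgeR, KO stood above both for 2004 genes and below both for 1929, del-cIDR for 733 and 894, and WT for 198 and 188. On the deposited scale KO stood above both for 3 genes and below both for 285, del-cIDR for 0 and 4, and WT for 1 and 0. These counts share libraries and are not independent. The 8 tested peaks on chromosome Y all had a higher mean m6A ratio in KO than in WT, with a median difference of 0.38. Of all tested peaks, 78.7% were higher in KO. The chromosome was not called against the others (camera, adjusted p = 0.688 over 63 tests). Of the Y peaks with ratios too low to be tested, that at 1263192 to 1263434 was lower in KO (0.473 against 0.613). That at 2286980 to 2287266 was higher (0.818 against 0.427).

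Higher m6A ratios in KO than in WT over most peaks are what loss of a demethylase would give, which is a hypothesis here. Counting error of the m6A control is argued against. The median log2 change of the ratio without the added 1 was 0.20, which is 3.404 times its standard error from control reads, 0.059. A change of low-ratio peaks only is argued against too, since the lowest median among 5 equal groups of peaks by level was 0.121, in the group with the highest ratios. A larger change of low-ratio peaks is not argued against, since the added 1 shrinks their changes more. The spread between libraries of 1 genotype cannot be told apart from an effect of the genotype. The change on the log2(ratio + 1) scale, 0.13, was 1.03 times the largest gap between replicate medians, with 2 libraries per genotype. Scaling to the m6A control stays open as well, since before the control constant the median log2 change was -0.4775, a value that also holds the depth of the IP libraries, and the control's input reads enter the scaling of both tables.

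Lower scaled mRNA values in KO than in WT over most genes may come from the control RNA rather than the cells. KO had 1.178 times the mean gene reads of WT, but read numbers cannot decide the question. Gene reads were scaled by control reads of the same library, so depth cancels. The spread of the scaling control between libraries stays open, since the size of the change was 1.004 times the largest gap between replicate medians, that of del-cIDR. A lower mRNA content of KO cells also stays open and was not tested.

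After centring, more genes were called in opposite than in the same direction in KO and del-cIDR (363 and 200), and a different effect of losing the enzyme and losing its disordered region is a candidate explanation. This did not hold on the deposited scale (0 opposite, 1 the same) or with a single WT library for both comparisons (268 and 273 without WT replicate 1, 274 and 341 without WT replicate 2), where its values enter both comparisons with the same sign. A deviating KO or del-cIDR library is argued against, since the lowest ratio of opposite to same-direction calls without 1 of them was 1.808. Sequencing depth is argued against, since the ratio was 2.652 with all libraries thinned to the depth of the smallest. That value is from edgeR, with 183 opposite and 69 the same. On all reads edgeR gave a ratio of 1.759, with 679 and 386. Differences between clones or cultures of the genotypes stay open, untested.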
